A study of Homo sapiens with 18 samples.

How the data were processed

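ATAC-seq of MCF-7 cells was analysed in 18 libraries, 3 in each of 6 groups: vehicle, E2, 4-OH tamoxifen, GNE-274, fulvestrant and GDC-0927. Per the labels, cells were deprived of hormone for 5 days and treated for 45 min, with 1 nM E2 or 100 nM of the other ligands. They were then detached and frozen, and an outside provider carried out transposition, library preparation and sequencing. The 3 libraries of a group were treated as independent, although the labels do not say that they came from separate cultures.

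A single table was used. It holds raw whole-number counts per region and library, which the authors deposited for a common set of 139553 regions. The submitters' processing notes name GSNAP for alignment and GRCh38. The peak caller, the counting program, the read filters and any shift of the Tn5 ends are not given in the sources used here. In each library more than 50% of counts from 1 to 19 were even (52.4 to 72.5%), and the highest share was that of fulvestrant 1. The authors also deposited a score per region and group, −log10 of a peak p-value with −1 where the group had none. It was present in all 6 groups for 76213 regions (54.6%) and in only 1 group for 21711 (15.6%). The deposited position code has 8 values and no key. Code 1 was used as the class next to gene ends because its regions lay a median of 322 bp from the nearest end of their gene.

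Regions were given the gene symbol of the authors (78534 regions) or, where there was none, the nearest protein-coding gene body within 100 kb of the RefSeq annotation of GRCh38 patch 14 (40204). No gene was given to 20815 regions. Of the 19264 symbols in the table, 19211 (99.7%) matched the annotation.

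Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, filterByExpr left out 94 regions, and 139459 were fitted together over all 18 libraries with a term per group. Quasi-likelihood F tests were made for 10 comparisons, and p-values were adjusted by the Benjamini-Hochberg method over all tested regions, with a threshold of 0.05. The biological coefficient of variation was 0.187. Every adjusted p of a single region in the text comes from this edgeR fit unless another tool is named. log2 CPM used a prior count of 2. DESeq2 1.42.0 and limma 3.58.1 (limma-trend) were run as alternatives. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

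Regions named in the text follow a rule. For each comparison these are up to 10 regions with the largest positive and up to 10 with the largest negative log2 change among those past the threshold. Their 3 libraries must lie all above or all below those of the other group, and their mean log2 CPM above the median of 2.11. In addition, 24 genes are followed whatever their result, each with its highest-count code 1 region and the other region with the smallest F test p. This rule, the comparisons, the gene lists and most of the other settings tried were chosen before the data were examined. The rule and the genes of regions had been planned with distances to transcription start sites. Code 1 and the authors' symbols or nearest gene bodies replaced these after the deposited table was seen. Genes ranked by their number of E2 regions, the regions that make up small counts on gene lists, and other GREB1 regions were chosen after their values were seen.

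The 15 gene lists were tested in each comparison with camera from limma, with a preset correlation of 0.01 and with an estimated correlation, and with fry. Adjusted p-values cover 15 lists and 10 comparisons. Camera asks whether the regions of a list rank above or below all others. Fry asks whether they move on balance in a single direction, without comparing them with other regions. Position was tested by Fisher's exact test, and the 36 position tests were adjusted together. For sets of regions that E2 changed, the mean log2 CPM of each library was compared between groups with 95% intervals from the spread within the 6 groups and by exact permutation, for which 3 against 3 gives 0.1 at the least. Enrichment of genes by their number of regions used exact hypergeometric tests.

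All ligands share the vehicle libraries. Chance similarity was therefore measured in 8 data sets simulated from the fitted means and dispersions, in which E2 kept its effect and the other ligands had none. Libraries were drawn independently, so structure shared by libraries apart from the treatment was not simulated. In a further simulated data set 200 regions per ligand were changed. Of regions changed 3-fold, 30.3 to 60.6% were recovered, and of those changed 2-fold 16.4 to 30.6%. For E2, 91.4% of the 3-fold regions above the median count were recovered. False calls made up 4.88 to 15.3% of the calls (11 of 72 for E2), more than the nominal level in most comparisons. Depth was 4.67 to 13.1 M counts per library (M, 1e6 counts).

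Other settings, fixed in advance, changed the normalisation (DESeq2 size factors, total count, cyclic loess), the test (DESeq2, limma-trend), the filter, the libraries fitted (the 6 compared only, or without each library in turn), a block for the replicate number, and the distance limit of the gene lists (10 kb). Some were added after seeing the data: thinning to the lowest total count, the first component of the libraries' deviations from their group means as a covariate, leaving out vehicle 1 and fulvestrant 1 together, a limit of 1 kb to gene ends, a choice of E2 regions without vehicle 2 and fulvestrant 2, and regions chosen as higher with E2 than with fulvestrant. Sequence motifs, the central part of regions and distances to transcription start sites, planned at the start, were not analysed here, because no genome sequence and no strand were used. Alternatives for a pseudocount did not apply to counts.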

Results

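Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in MCF-7 cells. MCF-7 is a breast cancer cell line that carries the estrogen receptor (ER). The cells were kept in hormone-deprived medium for 5 days and then treated for 45 min. There were 6 groups of 3 libraries each: vehicle (DMSO), estradiol (E2, the natural agonist), 4-OH tamoxifen, fulvestrant, and the test compounds GDC-0927 and GNE-274. E2 was given at 1 nM and the other 4 ligands at 100 nM, so comparisons with E2 also differ in dose. The labels do not say whether the 3 libraries of a group came from separate cultures. The table held 139553 regions, 250 to 1632 bp wide with a median of 269 bp, and 139459 of them had enough counts to be tested.

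Total counts in the 3 libraries (M, 1e6 counts) were 4.67, 8.95 and 7.96 M for vehicle and 13.1, 9.43 and 5.96 M for E2. They were 11.98, 10.6 and 5.68 M for 4-OH tamoxifen and 12.01, 8.08 and 6.16 M for GNE-274. Fulvestrant had 5.91, 8.86 and 9.13 M, and GDC-0927 had 9.65, 7.86 and 5.90 M. The median count per region was 19 to 54 per library. Across libraries of a group the biological coefficient of variation was 0.187. Values are counts scaled to library size (CPM, counts per 1e6) as mean ± SD (n = 3), and fold changes are on the log2 scale with their standard error (SE). Positions are on GRCh38. The errors cover variation between these libraries and counting, not variation between experiments.

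The first comparison asked which regions respond to estradiol. E2 increased accessibility far more often than it decreased it. The regions that opened lay mostly away from gene ends, and 72 belonged to genes on a list of ER targets, such as GREB1, PGR, TFF1, IGFBP4 and RARA. ESR1, FOXA1 and GATA3, which encode ER itself and the factors that work with it, had no changed region among the pair examined for each gene. With edgeR, 1468 regions rose and 84 fell after E2. The median log2 fold change of the regions that rose was 1.67, a 3.17-fold increase, and 1196 rose more than 2-fold. In 1550 of the 1552 regions all 3 E2 libraries lay on the same side of all 3 vehicle libraries, a separation that 10% of unchanged regions reach by chance. The regions were called on these same libraries, so the separation largely follows from the choice and is no separate support. An unadjusted p under 0.05 was found for 10163 regions. DESeq2 called 1636 regions and limma 1552.

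GREB1, an estrogen-induced gene widely used to read out ER activity, had 8 regions that rose among its 22. At the GREB1 region on chromosome 2 from 11498610 to 11498888, CPM was 5.76 ± 1.1 with vehicle and 39.3 ± 2.6 with E2. This was a log2 change of 2.80 (SE 0.16, adjusted p = 2.6e-13). The region with the highest count at the gene's end, from 11532527 to 11532834, went from 3.39 ± 1.1 to 18.2 ± 2.4 CPM (log2 change 2.46, SE 0.26, adjusted p = 1.1e-07). PGR encodes the progesterone receptor. Its region on chromosome 11 from 101034134 to 101034436 rose from 2.34 ± 1.1 to 12.9 ± 1.9 CPM (log2 change 2.46, SE 0.32, adjusted p = 3.8e-06). TFF1 encodes a secreted peptide of the mucosa. The region at its end on chromosome 21 from 42366674 to 42366943 rose from 13.5 ± 4.0 to 36.0 ± 3.2 CPM (log2 change 1.38, SE 0.17, adjusted p = 2.9e-06).

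Among the other genes followed whatever their result, IGFBP4, which encodes a binding protein of insulin-like growth factors, rose at a region by 2.22 on the log2 scale. RARA, a retinoic acid receptor, rose by 1.85, PDZK1, a scaffold protein, by 2.14, and CA12, a carbonic anhydrase, by 2.14. Regions of XBP1 (2.24), MYC (1.44), CTSD (1.95) and SIAH2 (1.59) also rose. The highest-count regions at the ends of XBP1, MYC and SIAH2 were not called. Their log2 changes were 0.06, −0.03 and 0.22. This covers 1 code 1 region per gene, of 3 for XBP1, 4 for MYC and 2 for SIAH2. The calls at NRIP1 (2.67), at FOS (0.93) and at the end of CA12 (0.75) ended when single libraries were left out. NRIP1 was lost without vehicle 1, 2 or 3 or E2 2. FOS was lost without vehicle 1 or 2 or E2 1 or 2, and the CA12 end without vehicle 1, 2 or 3 or E2 2 or 3. No region examined for ESR1, FOXA1, GATA3, CXCL12, KRT13, EGR3, CCND1, CYP1A1, ACTB or GAPDH was called, and CYP1B1 had 0 regions. The EGR3 region on chromosome 8 starting at 22678325 (log2 change 1.90, adjusted p = 0.0615) and the GATA3 region on chromosome 10 starting at 8073806 (log2 change −1.03, adjusted p = 0.0605) were close to the threshold and passed it without vehicle 2 (0.0350 and 0.0341).

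The strongest gains among well-covered regions lay in or next to genes such as TTC39A and ITPK1, and NHERF1, which is on the list of ER targets. The region of TTC39A on chromosome 1 from 51321425 to 51321685 went from 0.412 ± 0.43 to 9.05 ± 1.7 CPM, a log2 change of 4.72 (SE 0.48, adjusted p = 4.6e-08). The region of ITPK1, an inositol phosphate kinase, on chromosome 14 from 93017382 to 93017671 went from 2.49 ± 0.26 to 35.8 ± 4.3 CPM (log2 change 3.85, SE 0.22, adjusted p = 2.6e-13). The other 8 of the top 10 belonged to SNX24, CAMTA1, NHERF1, THADA, ARID1B, TGIF2, JAK1 and AFF3, with log2 changes from 3.46 to 3.83. Losses were smaller. The ARFGEF3 region on chromosome 6 from 138227592 to 138227860 fell from 12.6 ± 2.9 to 5.50 ± 0.91 CPM (log2 change −1.20, SE 0.21, adjusted p = 0.00048). The largest loss, 2839 bp from CD24 on chromosome 6 starting at 106966714 (log2 change −1.67, adjusted p = 0.0052), was lost without vehicle 3 (0.0835) or E2 1 (0.0617). A region 1818 bp from VMP1, a gene of autophagy, on chromosome 17 starting at 59844073 fell from 93.4 ± 19 to 47.1 ± 8.4 CPM (log2 change −0.99, adjusted p = 2.9e-05). A region of CTNND2 on chromosome 5 starting at 11733786 fell by 1.07 (adjusted p = 0.00027).

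**Figure D1:**
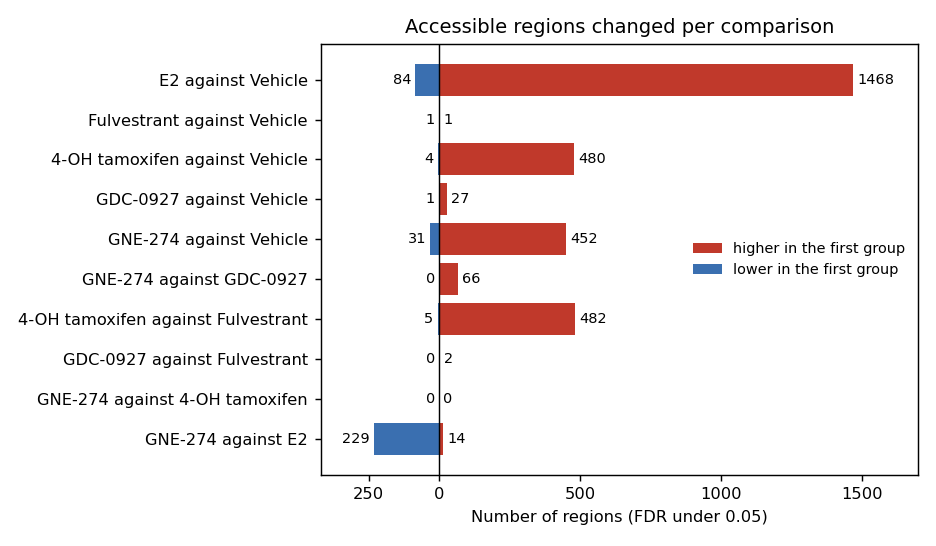
Number of regions called at an FDR under 0.05 in each of the 10 comparisons, with bars to the right for regions higher in the group named first and to the left for regions lower. E2 against vehicle has 1468 higher and 84 lower regions, and GNE-274 against 4-OH tamoxifen has 0.

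Some genes held many of the regions that E2 opened. A region's gene is the symbol given by the authors or, where they gave none, the nearest protein-coding gene within 100 kb. The 1468 regions fell on 939 genes, and 214 genes had at least 2. CXXC5, a zinc finger gene, had 15 of its 22 regions higher (exact hypergeometric p = 6.8e-21 after Bonferroni correction over 21307 genes). GSE1 had 17 of 82 (4.0e-13) and ITPK1 13 of 36 (7.3e-13). GREB1 had 8 of 22 (8.8e-07), TPD52L1 8 of 24 (2.0e-06), WWC1 7 of 25 (0.00012), NHERF1 5 of 10 (0.00066), CA12 5 of 12 (0.0020) and KDM4B 5 of 16 (0.011). Of genes with 4 regions, NAIF1 (4 of 7, 0.0089) and SLC35F6 (4 of 8, 0.018) passed. MSI2 had 6 of 54 (0.481), and CUX1, NCOR2 and PVT1 had 5 each (adjusted p = 1), which did not pass. These genes were ranked after the calls were made, and neighbouring regions are not independent.

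Genes induced by estrogen responded as a group. Of 440 tested regions of 44 ER target genes, 72 rose and 0 fell, and 29 of the 44 genes had at least 1 region that rose. TPD52L1 and GREB1 had 8 each, WWC1 7, CA12 and NHERF1 5 each and MYC 4. Adjusted over the list alone, 116 regions were higher. The median log2 change of the list was 0.38. A camera test, which compares the list with all other regions, gave an adjusted p of 3.5e-25 with the preset correlation and 0.00026 with an estimated correlation. A fry test, which asks only whether the regions of a list move on balance in a single direction, gave 3.7e-06. Both sets of p were adjusted over 15 lists in 10 comparisons. Of the 158 regions of genes that estrogen represses, 0 were called by edgeR, also when adjusted over the list alone. Their median was −0.15 (camera adjusted p = 8.7e-05, adjusted p = 0.132 with an estimated correlation, fry 0.036).

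Lists of other pathways held fewer changed regions after E2 than the ER list, and several shared genes with the ER list. Over all tested regions 1468 of 139459 rose. Immediate early genes had 7 of 122 regions higher (11 adjusted over the list alone), namely 4 of MYC and 1 each of FOS, FOSL2 and KLF4, and camera gave an adjusted p of 0.087. The mixed fry test, which asks whether regions change in either direction, gave adjusted p = 3.1e-16 for this list, 7.5e-14 for luminal genes and 9.5e-05 for the unfolded protein response. The luminal genes, which mark the cell type that MCF-7 resembles, had 8 of 259 higher (11 higher and 4 lower over the list alone). GRHL2 had 3 of these, and ELF3, KRT8, KRT18, TFAP2C and ZNF217 had 1 each. Genes of the unfolded protein response had 3 of 59, all of XBP1. Aryl hydrocarbon receptor targets had 2 of 48, at AHRR (0.88) and TIPARP (1.65). Basal markers had 1 of 59, at TP63 (1.64), and housekeeping genes 1 of 90, at YWHAZ (0.91). MYC, FOS, XBP1 and TIPARP are also on the ER list. Over the list alone the counts were 4 higher and 1 lower, 3, 3 and 1 for these 4 lists. With a limit of 10 kb to the gene, fewer of these calls remained: 3 of 58 for immediate early genes, 3 of 172 for luminal genes, 1 of 36 for the unfolded protein response and 0 of 37 for the aryl hydrocarbon receptor. The basal and housekeeping lists kept 1 each, and the ER list had 60 of 298. Blood markers (45 regions), fibroblast markers (71) and genes of the cell cycle (61), cholesterol synthesis (83), heat shock (41), p53 (49) and interferon response (37) had 0 regions called by edgeR. Apart from the ER list and the estrogen-repressed list, no list had an adjusted camera p under 0.05 after E2.

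E2 opened regions away from genes' ends. The authors gave each region a position code without a key, and regions of code 1 lay a median of 322 bp from the nearest end of their gene. Of the regions that rose, 9.60% had code 1, against 21.4% of tested regions (odds ratio 0.387, Fisher's exact test, adjusted p = 2.9e-32 over 36 position tests). Within deciles of mean count the odds ratio was 0.307. Only 4.50% lay within 1 kb of an end of a protein-coding gene, against 16.1% of tested regions (odds ratio 0.244, adjusted p = 1.4e-42). Code 3, the most frequent code, covered 52.9% against 40.8% (odds ratio 1.64, adjusted p = 1.2e-19). The regions opened by 4-OH tamoxifen and GNE-274 had 6.88% and 8.19% in code 1. The E2 regions were called as peaks in vehicle less often than regions at large. They were chosen as higher with E2 than with vehicle, so a low share in vehicle and a high share in E2 largely follow from the choice. The authors' peak p-value was present in vehicle for 48.0% of the E2 regions and in E2 for 98.7%. The share was 53.4% in fulvestrant, 60.8% in GDC-0927, 79.1% in GNE-274 and 83.5% in 4-OH tamoxifen. Of all 139553 regions, 95211 had it in vehicle and 110222 in E2. For fulvestrant, GDC-0927, GNE-274 and 4-OH tamoxifen these counts were 100364, 97799, 108162 and 111894. Mean depth also differed, from 7.19 M counts with vehicle to 9.48 M with E2, and the peak calls were not adjusted for it here.

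**Figure D2:**
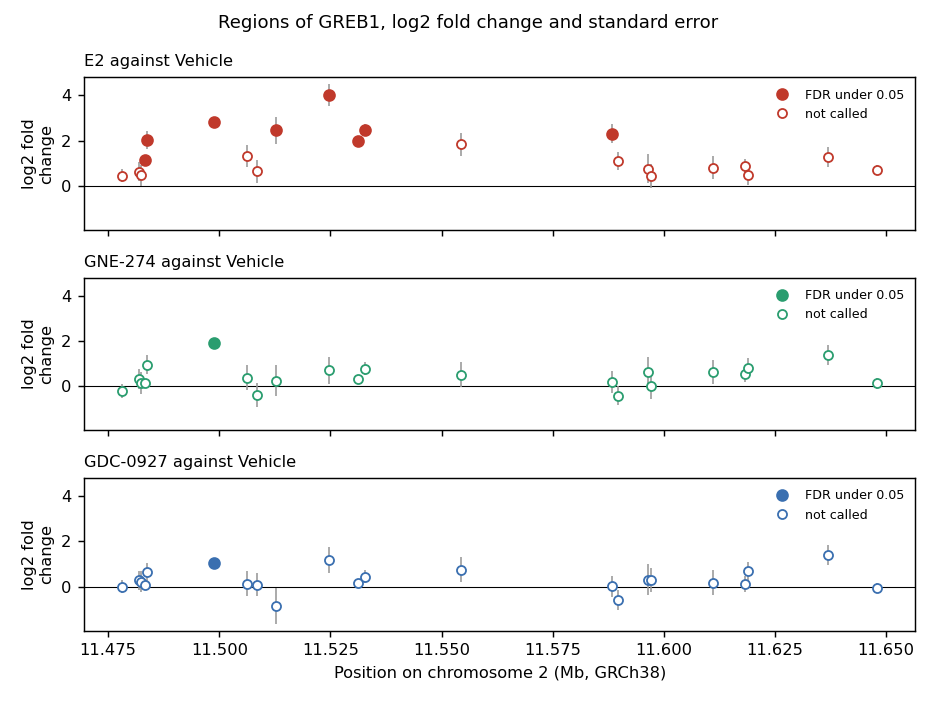
Log2 fold change against vehicle (points, with SE as bars) of the regions of GREB1 along chromosome 2 in megabases, for E2, GNE-274 and GDC-0927. Filled points passed an FDR of 0.05: 8 regions with E2, and with GNE-274 and GDC-0927 only the region starting at 11498610.

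4-OH tamoxifen, the active metabolite of tamoxifen, blocks ER in the breast but acts as a partial agonist elsewhere. After 45 min in these cells its called gains lay mostly at E2 regions, and almost no region was called lower. PGR, GREB1, IGFBP4, RARA, PDZK1 and CA12 gained accessibility at the same regions as with E2, with smaller log2 changes. At single regions 4-OH tamoxifen was not tested against E2. TFF1, XBP1, MYC, CTSD and SIAH2 did not pass. With edgeR, 480 regions rose and 4 fell, and 7581 had an unadjusted p under 0.05. The median log2 change of the regions that rose was 1.75. Of the 480, 462 were also called higher with E2, where 5.05 would be shared if the calls were independent. At most 1 call was shared with E2 by simulated ligands without effect. Counting changes below the threshold, 98.6% of the 1468 regions that rose with E2 had a positive log2 change (median 0.97). The share was 94.2% in 1560 regions chosen without vehicle, as higher with E2 than with fulvestrant (median 0.78). DESeq2 called 523 regions and limma 500.

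At the GREB1 region starting at 11498610, 4-OH tamoxifen gave 21.1 ± 0.48 CPM (log2 change 1.91, SE 0.16, adjusted p = 6.5e-09). At PGR it gave 7.76 ± 1.9 CPM (log2 change 1.72, SE 0.32, adjusted p = 0.0041). The end of GREB1 was not called (log2 change 0.76, adjusted p = 0.675), nor was the end of TFF1 (0.43, adjusted p = 0.824). Named gains over 2.9 lay at TTC39A (4.12), SNX24 (3.77), AFF3 (3.38), CAMTA1 (3.35), CIMIP5 (3.03), NR5A2 (2.99), SPINK4 (2.96), ZNF706 (2.95), ARID1B (2.93) and JAK1 (2.93). The loss 52035 bp from PEX2 on chromosome 8 starting at 77053079 (log2 change −1.28, adjusted p = 0.0418) ended without vehicle 1 or 2 or any of the 3 4-OH tamoxifen libraries. On the ER list 20 of 440 regions rose (26 adjusted over the list alone), in 18 genes. Camera gave an adjusted p of 0.00062, or adjusted p = 0.161 with an estimated correlation, and fry gave 0.036. The count on the list was 13 without vehicle 2. The luminal list had 2 regions higher (2 higher and 1 lower over the list alone), both of GRHL2, and the aryl hydrocarbon receptor list 1, at TIPARP (1 over the list alone). With a limit of 10 kb both lists had 0, and the ER list 17 of 298.

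GNE-274, a test compound of the same study, also had its called gains mostly at E2 regions. The genes were those seen with 4-OH tamoxifen: GREB1, PGR, IGFBP4, RARA, PDZK1 and CA12 gained accessibility, while TFF1, XBP1, MYC, CTSD and SIAH2 did not pass. With edgeR, 452 regions rose and 31 fell, and 11752 had an unadjusted p under 0.05. The median log2 change was 1.72 for the regions that rose and −1.17 for those that fell. Of the 452, 426 were also higher with E2 (4.76 if independent), and 385 were also higher with 4-OH tamoxifen (1.56 if independent). Counting changes below the threshold, 98.2% of the 1468 regions that rose with E2 had a positive log2 change (median 0.92). The share was 92.0% in 1560 regions chosen without vehicle, as higher with E2 than with fulvestrant (median 0.68). The number of changed regions was 743 without vehicle 2 and 281 when only the 6 libraries compared were fitted.

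With GNE-274 the GREB1 region starting at 11498610 had 21.3 ± 2.8 CPM (log2 change 1.91, SE 0.17, adjusted p = 9.3e-09) and the PGR region 8.20 ± 2.4 CPM (log2 change 1.77, SE 0.33, adjusted p = 0.0035). The end of GREB1 (0.76, adjusted p = 0.430) and the end of TFF1 (0.28, adjusted p = 0.710) were not called. Besides TTC39A (4.15), SNX24 (3.57), CAMTA1 (3.38) and AFF3 (3.27), a region 11083 bp from LAPTM4B, a lysosomal membrane protein, rose by 3.15, from 1.80 ± 0.81 to 16.97 ± 1.5 CPM (chromosome 8, 97764280 to 97764705, adjusted p = 3.7e-09). The region near PEX2 fell from 8.56 ± 2.2 to 2.55 ± 0.14 CPM (log2 change −1.71, SE 0.31, adjusted p = 0.0025). The LINC01435 region on chromosome 10 starting at 107728935 fell by 1.17 (adjusted p = 0.0049), a call lost without GNE-274 3. Other named losses (GLT8D2, CSMD3, NIBAN1, PRDM1 and 4 regions with no protein-coding gene within 100 kb) each ended in at least 4 of the 6 fits that left out a library. On the ER list 18 regions rose (23 adjusted over the list alone), in 16 genes. Camera gave an adjusted p of 0.042, or adjusted p = 0.667 with an estimated correlation, and fry gave 0.065. The luminal list had 1 region higher, of GRHL2, and the aryl hydrocarbon receptor list 1, at TIPARP. Over these lists alone the counts were 1 and 2, and for immediate early genes 1. Within 10 kb both had 0, and the ER list 15 of 298.

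GNE-274 and 4-OH tamoxifen were compared directly to see whether the compounds differ at the same dose and time. No single region was called. At GREB1, PGR, IGFBP4 and CA12 their mean CPM differed by less than the sum of the SDs. edgeR called 0 regions, with 4863 at an unadjusted p under 0.05, and DESeq2 and limma called 0. In simulated data, regions changed 3-fold in either ligand were recovered in 58.0% of cases and regions changed 2-fold in 27.8%, so many differences of this size at single regions would be missed. Over the 1468 regions that E2 opened, the mean of GNE-274 minus 4-OH tamoxifen was −0.06 on the log2 scale (95% interval −0.13 to 0.01, exact permutation p = 0.3). Over 1560 regions chosen as higher with E2 than with fulvestrant it was −0.08 (−0.15 to −0.0028, exact permutation p = 0.1, the smallest that 3 against 3 can give). In this set fry gave an adjusted p of 0.058, and camera 0.0073 with the preset correlation and 0.061 with an estimated correlation. In the 1468 regions these were 0.136, 0.039 and 0.152.

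GNE-274 at 100 nM opened chromatin less than E2 at 1 nM. The shortfall was among the largest near MIR4429, in GSE1, TMPRSS3 and CXXC5 and at the end of GREB1, where GNE-274 stayed closer to vehicle than to E2. At the GREB1 region starting at 11498610 it lay closer to E2 on the log2 scale. With edgeR, 229 regions were lower with GNE-274 than with E2 and 14 were higher, with 8455 at an unadjusted p under 0.05. The median log2 difference of the lower regions was −1.09. The GSE1 region on chromosome 16 starting at 85464983 had 2.69 ± 0.47 CPM with GNE-274, 12.9 ± 2.2 with E2 and 1.92 ± 1.2 with vehicle (log2 difference −2.24, SE 0.29, adjusted p = 6.6e-05). The TMPRSS3 region on chromosome 21 starting at 42376364 had 7.57 ± 2.2 against 27.4 ± 0.74 CPM (−1.86, SE 0.22, adjusted p = 1.5e-05). The largest difference, −2.46 (adjusted p = 9.1e-05), lay 481 bp from MIR4429 on chromosome 2 starting at 11539800, between regions of GREB1. The end of GREB1 differed by −1.70, the region starting at 11498610 by −0.89 (adjusted p = 0.00062), and the end of TFF1 by −1.09 (adjusted p = 0.00072). On the ER list 26 regions were lower (80 adjusted over the list alone). Camera gave an adjusted p of 1.2e-19, or adjusted p = 0.00048 with an estimated correlation, and fry gave 9.1e-05. The luminal list had 3 regions lower and the immediate early list 1, and both had 0 within 10 kb. Over the list alone these were 6 lower and 1 higher, and 2 lower, and the basal and unfolded protein response lists had 4 and 2 lower. The count fell to 103 without GNE-274 1, 137 without GNE-274 2, 141 without GNE-274 3, and 122 without E2 2 or E2 3. Of the regions that were higher with GNE-274, the one near VMP1 starting at 59844073 (0.86, adjusted p = 0.0018) passed in each of these fits. The one at CTNND2 (0.96, adjusted p = 0.0066) was lost without GNE-274 2.

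Fulvestrant is an ER antagonist that also promotes degradation of the receptor. Few regions were called against vehicle, and GREB1, PGR and TFF1 had no called region among those examined. With edgeR, 1 region rose and 1 fell, and 7467 had an unadjusted p under 0.05, against a median of 6761.5 for simulated ligands without effect, which had at most 3 calls. DESeq2 and limma each called 2. In simulated data only 16.4% of regions changed 2-fold and 30.3% of those changed 3-fold were recovered in this comparison, the lowest shares of the 10. The region that fell lay 38913 bp from CYP2A7 on chromosome 19, from 40921144 to 40921561. It had 37.2 ± 6.6 CPM with vehicle and 10.3 ± 2.7 with fulvestrant (log2 change −1.86, SE 0.18, adjusted p = 7.1e-07). The region that rose lay in CAMTA1 on chromosome 1, from 7447866 to 7448152, with 0.929 ± 0.46 and 3.92 ± 0.15 CPM (log2 change 2.01, SE 0.33, adjusted p = 0.0499). That call ended without vehicle 1 (0.434), vehicle 3 (0.643), fulvestrant 1 (0.251), fulvestrant 2 (0.268) or fulvestrant 3 (0.124). At the GREB1 region starting at 11498610 fulvestrant gave 6.63 ± 0.43 CPM (0.25, adjusted p = 0.927), and at PGR 2.10 ± 0.20 CPM (−0.15, adjusted p = 0.980). No region of the ER list was called, also when adjusted over the list alone. Of the other lists only the aryl hydrocarbon receptor list had a region over the list alone, 1.

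GDC-0927, the other test compound, had few called regions, all but 1 of them E2 regions that opened, and closed the region that fulvestrant closed. Its changes below the threshold also leaned upward at E2 regions: 90.9% of the 1468 had a positive log2 change (median 0.47), and 78.6% of 1560 regions chosen without vehicle, as higher with E2 than with fulvestrant (median 0.33). Of the ER target genes only GREB1 had a called region. With edgeR, 27 regions rose and 1 fell, with 7063 at an unadjusted p under 0.05 and a median log2 change of 1.22 for those that rose. All 27 were also higher with E2, with 4-OH tamoxifen and with GNE-274. The region near CYP2A7 fell to 10.02 ± 0.85 CPM (log2 change −1.87, SE 0.18, adjusted p = 6.3e-07). It also fell with E2 (−0.93, adjusted p = 0.00054) but was not called with 4-OH tamoxifen (−0.28) or GNE-274 (−0.17). CAMTA1 rose to 5.15 ± 0.34 CPM (log2 change 2.40, SE 0.32, adjusted p = 0.00079) and the GREB1 region starting at 11498610 to 11.6 ± 0.96 CPM (1.05, SE 0.17, adjusted p = 0.011). OSTF1, on chromosome 9 starting at 75101051, rose from 3.98 ± 1.4 to 11.1 ± 2.1 CPM (1.40, SE 0.22, adjusted p = 0.0057). The calls at CAMTA1 and OSTF1 ended when only the 6 libraries compared were fitted (0.152 and 0.259). The largest change, at TTC39A (3.05, adjusted p = 0.0259), was lost without vehicle 2 (0.136), vehicle 3 (0.153) or GDC-0927 2 (0.369). A region 40216 bp from ADD2 rose by 1.40 (adjusted p = 0.0033), a call lost without vehicle 2 (0.0518). The count of changed regions was 9 without vehicle 2, 11 without GDC-0927 2 and 3 when only the 6 libraries were fitted, while DESeq2 gave 57 and limma 52. The ER list had 1 region higher (6 adjusted over the list alone, camera adjusted p = 0.789), and the luminal list had 1 lower over the list alone.

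GDC-0927 was set against fulvestrant to see whether these ligands, both with few calls, differ. Few regions separated them, and both were opened by E2 as well. With edgeR, 2 regions were higher with GDC-0927, with 6762 at an unadjusted p under 0.05, and DESeq2 called 10. The region near ADD2 on chromosome 2 from 70616296 to 70616568 had 11.7 ± 0.99 against 4.41 ± 0.77 CPM (log2 difference 1.42, SE 0.20, adjusted p = 0.0094). A region on chromosome 8 from 128142015 to 128142284, with no protein-coding gene within 100 kb, had 64.0 ± 8.0 against 36.5 ± 2.9 CPM (0.81, SE 0.12, adjusted p = 0.018). The first call ended without fulvestrant 2 or 3 or GDC-0927 2 or 3, and the second without any of the 6 libraries. The ER list had 0 regions called and 1 over the list alone.

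GNE-274 opened more chromatin than GDC-0927 at single regions, at sites near LINC00276, LAPTM4B and CACNG4 and in GREB1. With edgeR, 66 regions were higher with GNE-274 and 0 lower, with 5960 at an unadjusted p under 0.05 and a median log2 difference of 1.43. DESeq2 called 112, of which 2 were lower. The region of LINC00276, a non-coding RNA, on chromosome 2 from 14178790 to 14179075 had 9.86 ± 0.81 CPM with GNE-274 and 1.30 ± 0.77 with GDC-0927 (log2 difference 2.87, SE 0.32, adjusted p = 1.3e-05). The region near LAPTM4B differed by 1.95 (adjusted p = 1.6e-05) and that near the calcium channel gene CACNG4 by 1.76 (adjusted p = 3.4e-06). The region near CYP2A7 differed by 1.70 (adjusted p = 3.4e-06), but through a loss with GDC-0927. CPM there was 10.7, 10.3 and 9.06 with GDC-0927, 28.7, 34.2 and 36.1 with GNE-274 and 41.9, 29.7 and 40.1 with vehicle. GREB1 at 11498610 differed by 0.86 (adjusted p = 0.0070). The count was 19 without GDC-0927 1, 31 without GDC-0927 2, 34 without GDC-0927 3, 31 without GNE-274 2 and 40 without GNE-274 3. SPINK4 (1.85) and CAMK1G (1.66) were lost without GDC-0927 1, and CIMIP5 (1.78) without GDC-0927 1 or 2. The ER list had 2 regions higher (6 adjusted over the list alone, camera adjusted p = 0.202), and the luminal list had 1 over the list alone.

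4-OH tamoxifen opened chromatin at many regions where fulvestrant did not. PGR, GREB1, RARA, CA12 and IGFBP4 were among them. With edgeR, 482 regions were higher with 4-OH tamoxifen and 5 lower, with 6963 at an unadjusted p under 0.05 and a median log2 difference of 1.58. At the GREB1 region starting at 11498610 the difference was 1.66 (SE 0.16, adjusted p = 9.3e-08), at the end of GREB1 1.35 (adjusted p = 0.0215) and at PGR 1.86 (adjusted p = 0.0014). The largest differences lay near CIMIP5 (3.03), CAMK1G (2.89) and SPINK4 (2.64) and in MPP7 (2.54). The region near ZBTB46 was lower by −1.40 (adjusted p = 0.0198), a call that ended without any of the 4-OH tamoxifen libraries or fulvestrant 1 or 3. Of the ER list 17 regions were higher (26 adjusted over the list alone). Camera gave an adjusted p of 0.00041, or adjusted p = 0.161 with an estimated correlation, and fry gave 0.036. The luminal list had 2 regions higher (2 over the list alone, 0 within 10 kb). The heat shock and aryl hydrocarbon receptor lists had 0, or 1 each over the list alone.

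**Figure D3:**
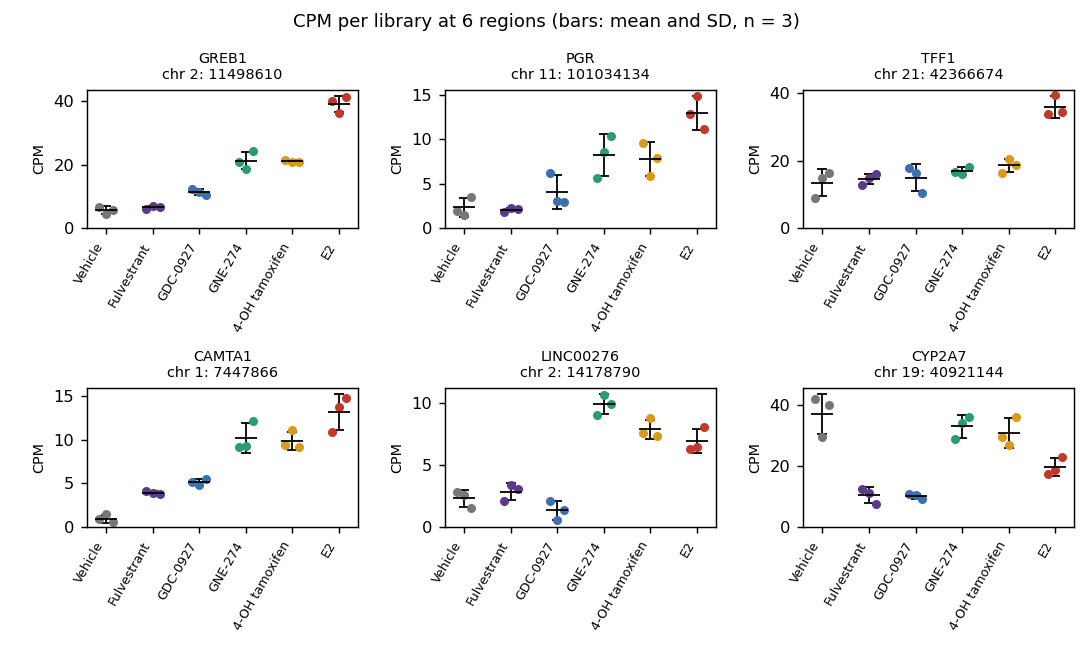
CPM per library at 6 regions in the 6 groups, with points for libraries and bars for mean and SD (n = 3). At GREB1, PGR and CAMTA1 E2 lies highest and vehicle or fulvestrant lowest, at TFF1 only E2 stands apart, and near CYP2A7 fulvestrant and GDC-0927 lie at 10.3 and 10.02 CPM against 37.2 with vehicle.

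The regions that E2 opened ordered the ligands. 4-OH tamoxifen and GNE-274 reached a similar partial opening, GDC-0927 less, and fulvestrant was close to vehicle. The mean log2 CPM of the 1468 regions, relative to vehicle, was 1.70 ± 0.05 with E2 (SD, n = 3), 1.07 ± 0.03 with 4-OH tamoxifen, 1.01 ± 0.05 with GNE-274, 0.54 ± 0.04 with GDC-0927 and 0.19 ± 0.02 with fulvestrant. The vehicle libraries had an SD of 0.05. On this scale 4-OH tamoxifen reached 63.1% of the E2 change, GNE-274 59.4%, GDC-0927 31.7% and fulvestrant 11.2%. The E2 libraries themselves helped to choose these regions, which favours a high E2 mean. These shares may thus be too low and the gaps to E2 too wide, which the intervals do not cover. 4-OH tamoxifen lay below E2 by −0.63 (95% interval −0.70 to −0.55) and GNE-274 by −0.69 (−0.76 to −0.62). GDC-0927 lay below GNE-274 by −0.47 (−0.54 to −0.40) and above fulvestrant by 0.35 (0.28 to 0.42). Fulvestrant lay below 4-OH tamoxifen by −0.88 (−0.95 to −0.81). For each of these differences the exact permutation p was 0.1, the smallest that 3 against 3 can give, with no overlap between libraries.

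These regions were chosen against the vehicle libraries that every ligand shares. The E2 libraries helped to choose every set given here. Simulated ligands without effect gave a mean of 0.035 (0.015 to 0.053) over regions chosen in this way. In 1560 regions chosen instead as higher with E2 than with fulvestrant, the means were 0.91 for 4-OH tamoxifen, 0.83 for GNE-274 and 0.37 for GDC-0927 (95% interval 0.30 to 0.45). Fulvestrant had 0.19 (0.12 to 0.26) in the first set and −0.07 (−0.15 to 0.01, exact permutation p = 0.2) in the second, which its own libraries helped to choose. In 912 regions chosen as higher with E2 than with GDC-0927 it had 0.06 (−0.02 to 0.15). Its interval lay above 0 in the first set alone, where it also lay above the highest simulated value. In 1225 regions chosen as higher with E2 without the use of vehicle 2 and fulvestrant 2, vehicle 2 itself lay 0.32 above the mean of vehicle 1 and 3, and the fulvestrant libraries 0.42, 0.35 and 0.49. Its median over the first set was 0.14, and 0.28 without vehicle 3.

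**Figure D4:**
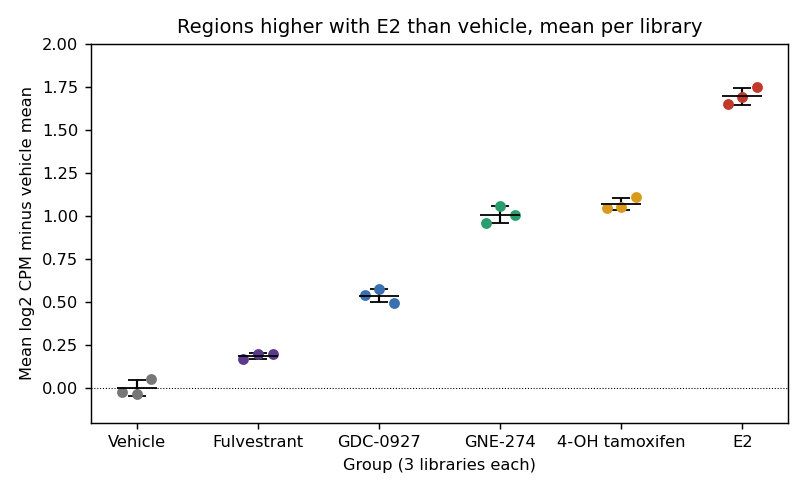
Mean log2 CPM of the 1468 regions higher with E2 than vehicle, minus the vehicle mean, for each library (points) with the group mean and SD (bars, n = 3). The groups run from 0.19 with fulvestrant through 0.54 with GDC-0927, 1.01 with GNE-274 and 1.07 with 4-OH tamoxifen to 1.70 with E2.

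Across all tested regions the responses to the ligands were correlated, in part because they share the vehicle libraries. Pearson r of the log2 changes was 0.660 for 4-OH tamoxifen and GNE-274, 0.649 for E2 and 4-OH tamoxifen, 0.646 for GNE-274 and GDC-0927 and 0.618 for E2 and GNE-274. It was 0.601 for 4-OH tamoxifen and GDC-0927, 0.582 for GNE-274 and fulvestrant, 0.560 for fulvestrant and GDC-0927, 0.541 for E2 and GDC-0927, 0.522 for 4-OH tamoxifen and fulvestrant and 0.487 for E2 and fulvestrant. Simulated ligands without effect gave 0.518 with each other and 0.455 with E2. These correlations are across regions, which are not independent replicates. The covariance exceeded the simulated value most for E2 and GNE-274 (by 0.055) and for 4-OH tamoxifen and GNE-274 (by 0.051). It did so least for E2 and fulvestrant (0.014) and for 4-OH tamoxifen and fulvestrant (0.012). By r the excess was largest for E2 and 4-OH tamoxifen, so the order depends on the measure. Simulated libraries were drawn independently, so structure of the libraries apart from the treatment can also add to the excess.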

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

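The tests of this part that use regions chosen without vehicle, thinned counts or a choice without 2 libraries were chosen after the result was seen, except the test of fulvestrant against vehicle in independently chosen regions, which was set before its result.

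Differences between the effects of 2 ligands were singled out for a closer look because a direct test of 1 ligand against the other found changed regions. GNE-274 and GDC-0927 differed in 66 regions, 4-OH tamoxifen and fulvestrant in 487, GDC-0927 and fulvestrant in 2, and GNE-274 and E2 in 243. Single libraries were not tested as extreme.

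Other splits of the same 6 libraries, 3 against 3, were tested for every comparison. There are 10 such splits, so the share that calls as many regions as the real grouping cannot be under 0.1. The real grouping alone reached its count in E2 against vehicle (1 of 10 splits, 1552 regions, highest other 687), 4-OH tamoxifen against vehicle (1, 484, highest other 0) and GDC-0927 against vehicle (1, 28, highest other 1). The same held for GNE-274 against GDC-0927 (1, 66, highest other 0), 4-OH tamoxifen against fulvestrant (1, 487, highest other 0), GDC-0927 against fulvestrant (1, 2, highest other 0) and GNE-274 against E2 (1, 243, highest other 2). In GNE-274 against vehicle 2 splits called as many (real 483, highest other 529), and in fulvestrant against vehicle also 2 (real 2, highest other 2274). In GNE-274 against 4-OH tamoxifen all 10 splits called 0. On the ER list other splits called at most 3 regions for E2 (real 72) and 0 for 4-OH tamoxifen (real 20) and GNE-274 (real 18).

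The split of fulvestrant 1, fulvestrant 3 and vehicle 2 against the other 3 libraries called 2274 regions against 2 for the real grouping, which points to a structure of the samples that is not the treatment. Against depth as its cause, the split called 1824 regions with all libraries thinned to 4.67 M counts, 1628 of them among the 2274. Against an exchange of vehicle 2 and fulvestrant 2, the region near CYP2A7 had 29.7 and 11.2 CPM in these libraries and that in CAMTA1 1.42 and 3.85, each nearest to its own group, but both regions were called with these labels. In 1225 regions higher with E2, chosen without both libraries, fulvestrant 2 minus vehicle 2 was 0.03 (95% interval −0.162 to 0.222), so an exchange stays open. Base composition of the fragments could be the cause: the median slope of chromosome 19 regions on the shared axis was −0.0798 against −0.006 for all regions, but no genome was used to test it.

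Regions lower with E2 than with vehicle were also lower with the other 4 ligands, with means of −0.40 for 4-OH tamoxifen, −0.42 for GNE-274, −0.35 for fulvestrant and −0.34 for GDC-0927. Simulated ligands without effect, sharing the vehicle libraries that chose the regions, had a mean of −0.295 (−0.347 to −0.234) at such regions: GDC-0927 lay within this range, fulvestrant at its edge and 4-OH tamoxifen and GNE-274 below it. In 53 regions lower with E2 than with fulvestrant, chosen without vehicle, the most negative mean of 3 ligands was −0.12 (4-OH tamoxifen, 95% interval −0.21 to −0.03). GNE-274 had −0.09 there (−0.18 to 0.01). The pattern was thus weaker in these regions, but the shared vehicle was not the only change. The choice used the fulvestrant libraries, which favours regions that fulvestrant does not lower (mean 0.22 there). E2 had −0.73 there against −0.95 in the first set. The loss can therefore not be assigned to the shared vehicle alone, and small effects of 4-OH tamoxifen and GNE-274 stay open.

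GDC-0927 and fulvestrant lay above vehicle at regions higher with E2, by 0.54 and 0.19. Against the shared vehicle as the cause for GDC-0927, the lower 95% bound was 0.298 in regions chosen without vehicle. Against depth, its mean with thinned libraries was 0.484. For fulvestrant the mean was 0.0643 in regions chosen as higher with E2 than with GDC-0927, with an interval that held 0 (−0.02 to 0.15). Simulated ligands without effect reached only 0.053 in the first set. In regions chosen without vehicle 2 and fulvestrant 2, vehicle 2 lay 0.32 above the mean of vehicle 1 and 3. The fulvestrant libraries lay 0.42, 0.35 and 0.49 above it. The choice and the baseline there used vehicle 1 and 3 alone, so these values are not on the scale of 0.19 and 0.053. For fulvestrant the explanation stays open. Whether GDC-0927 acts through ER at these regions stays open, since no ER binding was used here.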

How the results depend on the processing

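The alternatives that thin counts, add the deviation component as a covariate, leave out vehicle 1 and fulvestrant 1 together or choose E2 regions without vehicle were chosen after seeing the data. No result of a refit or a change of tool reversed. The mean of fulvestrant at E2 regions turned from 0.19 to −0.07 (95% interval −0.15 to 0.01) in regions chosen as higher with E2 than with fulvestrant, which its own libraries helped to choose. The counts for E2 against vehicle (1177 to 2143) and 4-OH tamoxifen against vehicle stayed within 1.5 times the main value, as did the counts of the ER list in fits of all libraries and the share of code 1.

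With the deviation component as a covariate the counts rose to 37 for fulvestrant against vehicle, 274 for GDC-0927 against vehicle and 1655 for GNE-274 against vehicle. They rose to 149 for GNE-274 against GDC-0927, 856 for 4-OH tamoxifen against fulvestrant, 13 for GDC-0927 against fulvestrant, 7 for GNE-274 against 4-OH tamoxifen and 619 for GNE-274 against E2. This component is estimated from the same residuals and lowers their spread by construction. With only the 6 libraries compared, which leaves fewer samples for the spread, counts were 1 for fulvestrant against vehicle, 3 for GDC-0927 against vehicle, 281 for GNE-274 against vehicle, 0 for GDC-0927 against fulvestrant and 1 for GNE-274 against 4-OH tamoxifen. With thinned counts they were 1, 14 and 1 for fulvestrant against vehicle, GDC-0927 against vehicle and GDC-0927 against fulvestrant. Leaving out vehicle 1 and fulvestrant 1 gave 1 for fulvestrant against vehicle and 1 for GDC-0927 against fulvestrant. Total counts alone and a block for the replicate number each gave 1 for fulvestrant against vehicle. DESeq2 gave 57 for GDC-0927 against vehicle, 112 for GNE-274 against GDC-0927 and 10 for GDC-0927 against fulvestrant, limma 52 for GDC-0927 against vehicle, and loess offsets 6 for GDC-0927 against fulvestrant. The cause was not tested for the other tools and normalisations.

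Without 1 library in turn the counts ran from 1177 (no vehicle 2) to 1386 for E2, 1 to 3 for fulvestrant, 360 to 386 for 4-OH tamoxifen, 9 to 22 for GDC-0927 and 338 to 743 (no vehicle 2) for GNE-274, each against vehicle. They ran from 19 (no GDC-0927 1) to 52 for GNE-274 against GDC-0927, 332 to 387 for 4-OH tamoxifen against fulvestrant, 0 to 1 for GDC-0927 against fulvestrant, 0 to 0 for GNE-274 against 4-OH tamoxifen and 103 (no GNE-274 1) to 197 for GNE-274 against E2. ER list regions ran from 57 to 69 with E2, 13 to 18 with 4-OH tamoxifen and 14 to 18 with GNE-274, and the share of code 1 from 8.99 to 11.2%. The median change at E2 regions ran from 0.93 to 1.18 for 4-OH tamoxifen, 0.89 to 1.15 for GNE-274, 0.14 to 0.28 for fulvestrant and 0.46 to 0.59 for GDC-0927. Pearson r ran from 0.541 to 0.785 for E2 and 4-OH tamoxifen, 0.430 to 0.776 for E2 and GNE-274, 0.354 to 0.699 for E2 and fulvestrant, 0.396 to 0.732 for E2 and GDC-0927 and 0.558 to 0.811 for 4-OH tamoxifen and GNE-274. It ran from 0.448 to 0.733 for 4-OH tamoxifen and fulvestrant, 0.501 to 0.779 for 4-OH tamoxifen and GDC-0927, 0.461 to 0.774 for GNE-274 and fulvestrant, 0.555 to 0.809 for GNE-274 and GDC-0927 and 0.436 to 0.768 for fulvestrant and GDC-0927, highest each time without vehicle 2.

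Of 124 calls at named regions, 32 were lost with only the 6 libraries, 30 with thinned counts, 22 without vehicle 1 and fulvestrant 1, 14 with the block, 10 with limma, 2 with total counts, 1 with loess, and 0 with DESeq2 or without a filter. Replicate numbers showed no general pairing: the median r of the libraries' deviations was 0.017 for same-number pairs and −0.0013 for other pairs. On the first component of the deviations, replicate 3 scored −92.6 with vehicle, −24.0 with E2 and −52.8 with 4-OH tamoxifen. It scored −79.5 with GNE-274 and −46.7 with GDC-0927, but 68.1 with fulvestrant. Depth fell with replicate number in E2, 4-OH tamoxifen, GNE-274 and GDC-0927, but not in vehicle or fulvestrant. A structure tied to replicate number in part of the groups thus stays open. Motifs, the central part of regions, start site distances and pseudocounts were not run. Most changes under 2-fold would be missed: at 1.5-fold, 1.49 to 6.72% were recovered in simulated data. Depth was not varied there, so its part in this was not tested.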

Other observations

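The tests of this part were chosen after the result was seen. The regions that E2 opened were not spread evenly over the chromosomes. Chromosome 16 held 94 of them where 43.3 were expected from its 4110 tested regions (odds ratio 2.28, Fisher's exact test, adjusted p = 1.3e-10). Without GSE1, the gene with the most such regions, it held 77 where 42.4 were expected. Chromosome 7 held 53 where 87.1 were expected (adjusted p = 0.00071) and chromosome 4 held 48 where 74.7 were expected (adjusted p = 0.0076). These tests treat regions as independent, which neighbouring regions are not, so their p-values may be too small.

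In a principal component analysis of all libraries the first component held 15.5% of the variance and the second 10.1%. Pearson r of log2 CPM between libraries of a group was 0.867 to 0.931. Fulvestrant 1 had 72.5% even values among counts from 1 to 19, where the other libraries had 52.4 to 63.9%. Without it the mean of fulvestrant at the E2 regions was 0.20, and GDC-0927 lay 0.34 above fulvestrant.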
